A study of Mus musculus with 4 samples.

How the data were processed

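The series holds 4 Affymetrix arrays of biotin-labelled liver RNA, 1 each for wild-type and liver-specific Myd88 knockout mice on control and high-fat diet. RNA of 4 to 5 mice per group was pooled before labelling, with mice chosen for RNA quality, per the labels' protocols. The values are log2 expression values per probe set as the authors deposited them, made by robust multi-array averaging (RMA) in Affymetrix Expression Console per the submitters' processing notes; the software version and the probe set library are not given in the sources used here. RMA corrects background, normalises by quantiles and summarises the probes of a probe set, so array-wide differences in brightness are removed and differences of dim probe sets are compressed. The sorted values of the 4 columns differed by up to 0.137 log2. No scanner files, background calls or detection p-values were used, so signal over background is unknown for each probe set, and slide or scan batches were not analysed here.

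Probe sets were named through the platform annotation paired with the value table. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none; those with several or none were given no gene name. Of those with 1 symbol, 23328 were found by Entrez identifier in the reference gene table and 0 symbols were changed by it. No genome build or coordinates were used, and probe sets are identified by their number. The 22180 distinct genes were each read from the probe set with the highest mean over the 4 arrays, which was a choice among several probe sets for 1082 genes. Genes whose mean log2 value was below the 40th percentile (3.47) were left out, and 13308 remained. Members of families with near-identical copies (Mup, Cyp2b, Cyp3a, Cyp4a, Saa, Hba, Hbb and H2 genes) share probe sequence, so values of Cyp2b9, Cyp2b13, Cyp4a14, Cyp4a31, Saa2, Saa3 and the H2 genes may mix copies and are uncertain.

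Samples were grouped by genotype and diet from the labels. Differences between 2 arrays (high-fat minus control diet in each genotype, knockout minus wild type on each diet, and the difference between the diet differences) are subtractions of log2 values. They have no replicate and no p-value, and genes were counted at 2-fold or more. The effects of diet over both genotypes and of genotype over both diets were fitted with limma 3.58.1 in R 4.3.3 (lmFit with genotype and diet as additive terms, eBayes, Benjamini-Hochberg adjustment at 0.05). This fit has 1 residual degree of freedom, which is the diet by genotype difference, and eBayes adds a prior shared over genes. Its p-values treat that difference as error, so they measure spread between these pooled arrays and not between mice, and a gene that responds to diet in 1 genotype alone has a large error. Correlations across genes were computed between differences that share no array. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

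The tests, alternatives, gene lists and the rule for named genes were set before the data were examined, except where stated otherwise. The text could name the 10 highest and 10 lowest genes by the smaller of the 2 differences for diet and for genotype, the 5 highest and 5 lowest of each difference between 2 arrays and of the difference of differences, Myd88, and from each list up to 4 members with the largest differences and any that passed limma's test. Predicted genes and non-coding RNA were counted without being named, except Xist, which with the Y-linked genes Eif2s3y, Uty and Kdm5d is named outside this rule and was chosen after the data were examined. Of 41 lists of pathways and cell types, 40 had at least 3 measured genes and were described; the erythroid list had fewer. They held 723 distinct genes, 566 of them measured. Some genes are in more than 1 list, such as Lcn2, Fgf21, Me1, Cdkn1a, Igfbp1, Cyp2b9 and Cyp2b13. Limma's p-values were also adjusted within each of the 40 lists alone, for diet and for genotype. This adjustment was not among the tests set beforehand, and members that passed it are named too. No correction was made over the lists, so some members pass this adjustment by chance. A list's median difference was given its percentile among 10000 random lists of equal size matched on mean expression in 20 bins, and was said to be outside the random range below the 2.5th or above the 97.5th percentile. This describes these arrays and is no test, and 5% of lists of unrelated genes fall outside by chance. Members of a pathway or cell type list can vary together, so more of these lists may fall outside without an effect of diet or genotype. Per difference between 2 arrays, 16 lists for diet in wild type, 11 for diet in knockout, 12 for genotype on control diet and 8 for genotype on high-fat diet were outside; lists the text does not name for a difference were within the range there. Lists for a wider set of pancreas genes, skeletal muscle, gastric and gland mucosa and female-biased liver genes were added after the data were examined.

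The limma step was tested on simulated data for the diet effect over 13308 genes with 200 genes changed. It called 94% of genes changed 2-fold and 100% of those changed 4-fold, with 19 unchanged genes called, and 5.54% of unchanged genes had an unadjusted p under 0.05. The simulated arrays were additive with noise drawn from the fitted prior, so no diet effect depended on genotype beyond that noise. The share called also depends on the number of changed genes. It is therefore no measure of power on the real arrays, where 68 genes had a mean diet difference of at least 2-fold. The list step, tested on the diet difference in wild type, put 7.5% of 200 unshifted random lists outside the range and 95.5% of 200 lists shifted by 0.3 log2. The alternatives were cyclic loess between arrays, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, an intensity trend in eBayes, an adjusted p of 0.1, an added 1.5-fold minimum, counts at 1.5-fold and 3-fold, and Spearman's rho for the correlations. Further alternatives, without marker genes of pancreas, muscle and gastric mucosa and without small RNA probe sets, were added after the data were examined.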

Results

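Liver RNA from C57Bl6 mice was profiled on 4 Affymetrix gene arrays, 1 for each combination of genotype and diet. The wild-type mice carried floxed Myd88, and the knockout mice carried the same floxed gene together with a Cre recombinase driven by the albumin promoter, which removes the gene in hepatocytes. Myd88 encodes the adaptor that links Toll-like receptors and interleukin-1 receptors to inflammatory signalling. Each genotype was fed a control diet with 9.4% fat or a high-fat diet with 60% fat, and the animals were 16 weeks old. Each array held the pooled RNA of 4 to 5 mice, so the groups had 1 array each and no replicate; the number of arrays limits the precision. A pooled array averages over its mice, and the spread between the mice of a group was not measured. The deposited values were log2 expression values, with a median between 3.53 and 3.56 on each array, and the arrays correlated across all probe sets with a Pearson r between 0.985 and 0.990. After the filter on dim probe sets 13308 genes remained.

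The targeted gene was read first. Myd88 (probe set 17532137) had a log2 value of 6.10 in wild type and 5.91 in knockout on control diet, and of 6.44 in wild type and 6.23 in knockout on high-fat diet. The knockout value was lower by a log2 difference of -0.19 on control diet and -0.21 on high-fat diet, and it was higher on high-fat diet than on control diet by 0.33 in wild type and 0.32 in knockout. Both genotype differences had the sign of the labels and were smaller than the spread of single genes, whose central 95% lay between -0.45 and 0.41 on control diet. Where its probes lie relative to the deleted part was not analysed here, and probes outside that part check nothing. Other cells of the liver keep the gene, so these values are no check of the deletion.

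The first comparison asked which transcripts differed with the high-fat diet in both genotypes. Among the enzymes of fatty acid synthesis, which did not all differ the same way, some were lower on high-fat diet: Acacb, an acetyl-CoA carboxylase, by -1.48 in wild type and -1.45 in knockout, Me1, the malic enzyme that supplies NADPH, by -2.12 and -1.10, and Scd1, the stearoyl-CoA desaturase, by -1.57 and -0.87. The hormone gene Fgf21 was lower by -2.16 and -1.19, the leptin receptor gene Lepr by -1.47 and -1.30, and Csad, an enzyme of taurine synthesis, by -3.61 and -1.47. The clock gene Arntl was lower by -1.97 in wild type and just short of 2-fold in knockout, while Wee1, a cell cycle kinase gene, was higher by 1.43 and 1.99. Zfp992 was higher by 1.68 and 1.85, Clec2h by 1.28 and 1.67, the guanylate binding protein gene Gbp11 by 1.32 and 1.13, and Obp2a by 1.12 and 1.87. The other genes with large shared differences were Tubb2a, Ly6d, Cdkn1a and Cyp4a14 among those that were lower, and Klk1, Clps, Try4, Cpa1 and Pnliprp1, which are abundant in pancreas, among those that were higher. At least 2-fold differences of the same sign in both genotypes were found for 21 genes that were higher and 10 that were lower. The 21 higher genes included the pancreas genes just named and also Cela1 and Ctrb1 of the pancreas list.

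Across genes, the diet differences of the 2 genotypes, which share no array, correlated with a Pearson r of 0.241 and a Spearman rho of 0.188, and 55.1% of genes had the same sign in both; genes are not independent replicates. Of the 140 genes that were at least 2-fold different in wild type, 106 had the same sign in knockout. In limma's additive fit over all 4 arrays, which takes the diet by genotype difference as its error with 1 residual degree of freedom, 0 genes passed a Benjamini-Hochberg adjusted p of 0.05 for diet. The smallest adjusted p was 0.163, and 1238 genes had an unadjusted p under 0.05, against 665 by chance; 576 of them were higher and 662 lower on high-fat diet. The same limma fit after a cyclic loess normalisation between arrays called 70 genes, 41 higher and 29 lower, so this count depends on the processing. The degrees of freedom of the eBayes prior were 4.63 on the deposited values and 7.34 after loess. What changed the count was not tested.

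**Figure D1:**
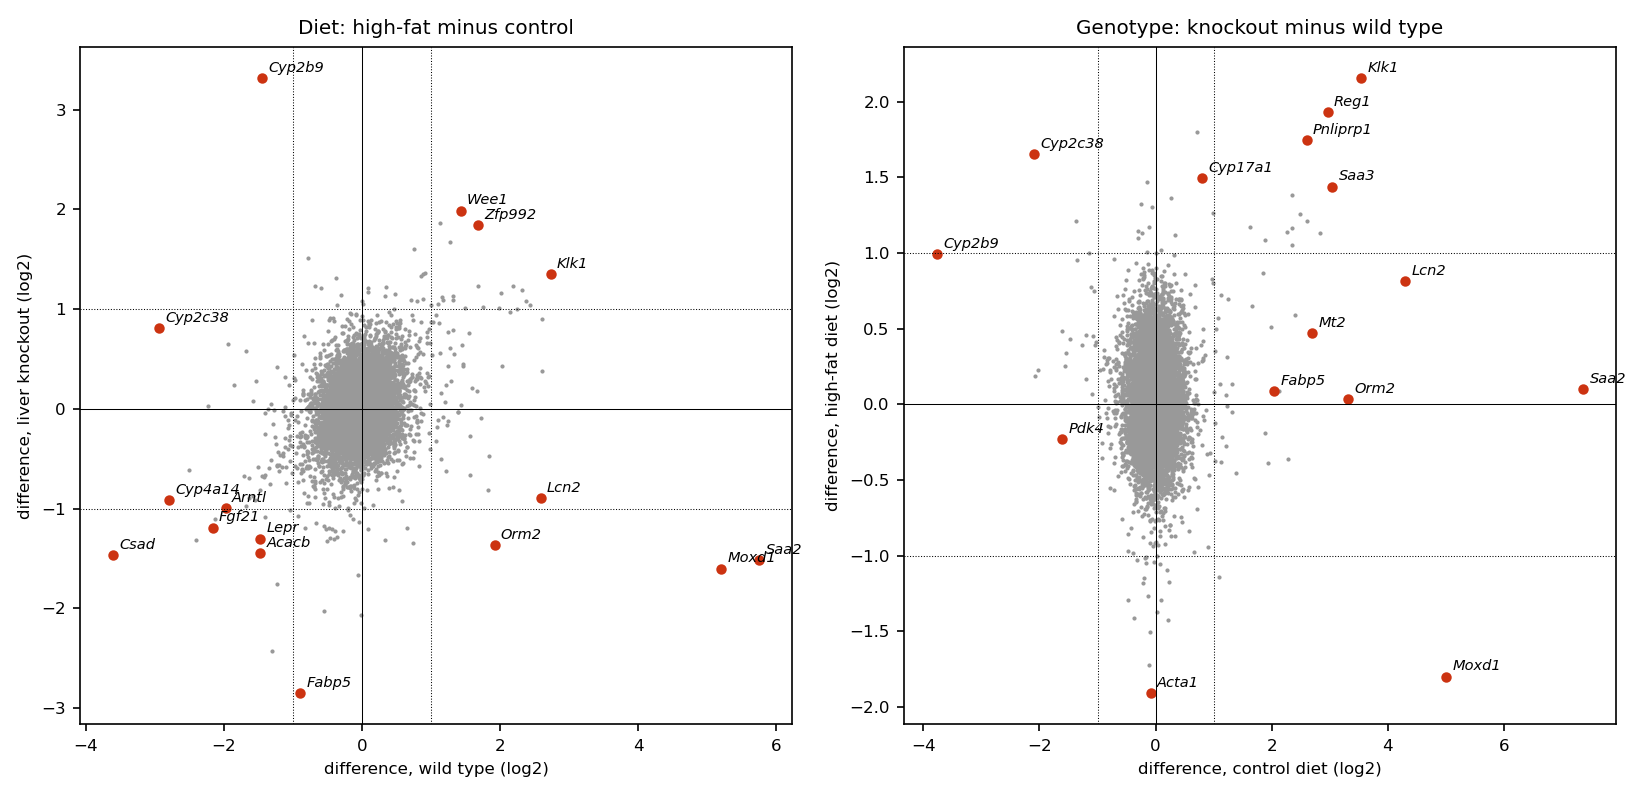
Each grey point is 1 of 13308 genes; the left panel sets the diet difference in wild type (x axis, log2) against that in knockout (y axis, log2), and the right panel sets the genotype difference on control diet against that on high-fat diet, with dotted lines at 2-fold. Named genes are in red: Arntl and Acacb lie low in both genotypes, and Saa2 lies at 7.37 on control diet and 0.10 on high-fat diet in the genotype panel.

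The genes were also grouped by the lists fixed in advance. Of 21 measured genes of lipogenesis and triglyceride synthesis, 17 were lower on high-fat diet in wild type and 13 in knockout, with medians of -0.25 and -0.07. None passed limma's test adjusted over all genes; 9 passed when adjusted over the list alone, of which 7 fell (Acacb, Me1, Scd1, Elovl3, Elovl5, Acss2 and Fasn) and 2 rose (Thrsp and Srebf1). Thrsp encodes a nuclear protein linked to lipogenesis and Srebf1 a transcription factor that drives it; they were higher by 0.94 (SE 0.12) and 0.71 (SE 0.13), with adjusted p over the list alone of 0.00395 and 0.00546 in limma, and higher in both genotypes. In wild type the list's median lay at the 0.01th percentile of 10000 matched random lists, and in knockout at the 3.87th, within their central 95%. The list of cholesterol synthesis and SREBP2 targets had medians of -0.29 and -0.19 with 17 and 16 of 19 members lower; 3 passed limma's test adjusted over the list alone, all of them lower (Sqle, Pmvk and Fdps, with log2 effects of -0.86, -1.04 and -0.60), and 0 when adjusted over all genes.

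Clock genes had the same direction in both genotypes for 16 of 17 measured members. Limma called 8 when adjusted over the list alone and 0 when adjusted over all genes: Per3, Ciart, Dbp, Tef and Usp2 rose, and Arntl, Nfil3 and Nr1d1 fell. Per3 was higher by 1.24 in wild type and 0.77 in knockout, and Ciart by 1.08 and 0.94. Arntl encodes the activator of the clock, and Nr1d1 a repressor of Arntl. The list's medians of 0.21 and 0.23 lay at the 99.99th and 99.4th percentile of random lists, and these medians hide members that went opposite ways.

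Ribosomal protein genes had medians of -0.19 and -0.22, with 16 and 15 of 17 members lower, and 0 passed either limma adjustment. Markers of Kupffer cells and macrophages had medians of -0.18 and -0.11, with 16 and 15 of 21 lower and 0 passing. Glucocorticoid and fasting responsive genes had medians of -0.19 and -0.26, but a mean of 0.08 in wild type, where Lcn2 and the metallothionein genes Mt1 and Mt2 were high; Igfbp1 and Cdkn1a fell when adjusted over the list alone, and 0 members passed over all genes. Markers of B and plasma cells had medians of 0.40 and 0.22 over 5 members, of which 3 were higher, and Ighm rose when adjusted over the list alone, by 0.50 (SE 0.12). In bile acid synthesis, whose median was within the random range in both genotypes, Cyp7a1, the rate-limiting enzyme, rose by 0.49 in wild type and 0.75 in knockout, and Akr1d1 by 0.49 and 0.80; both passed limma's test adjusted over the list alone (adjusted p 0.0320 for each). Insulin signalling had 3 of 13 members that fell when adjusted over the list alone, which were Irs1, Irs2 and Igfbp1. Pancreas transcripts were higher on high-fat diet in both genotypes, with medians of 1.99 and 1.01 over 9 markers, and 8 of the 9 passed when adjusted over the list alone.

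In wild-type mice alone, high-fat diet went with 65 genes at least 2-fold higher and 75 at least 2-fold lower; these differences between single arrays have no replicate check. The highest were Saa2, an acute phase serum amyloid gene, by 5.76, Moxd1 by 5.20, Klk1 by 2.73, the complement gene C4a by 2.61 and the pancreatic carboxypeptidase gene Cpb1 by 2.61. The lowest were Csad, Cyp2c38 (-2.94), Cyp4a14 (-2.80), Gstm3 (-2.50) and Tubb2a (-2.40). The acute phase list had 18 of 24 members higher, 9 of them at least 2-fold, and a median of 0.26, above all of the random lists. The complement and coagulation list had a median of 0.16 (99.8th percentile). Targets of the drug sensing receptors CAR and PXR had a median of -0.39, with 13 of 20 lower, 6 of them at least 2-fold, and 7 higher. Against the median, Cyp2c54 was higher by 0.83 in wild type and 0.68 in knockout, and Nr1i3 by 0.57 and 0.62. PPARalpha targets had a median of -0.16, with 20 of 25 lower and Cyp4a14, Fgf21, Cyp4a31 and Acot1 the lowest. In knockout, Cyp4a14, Fgf21 and Cyp4a31 were lower too, by -0.91, -1.19 and -0.89. These 5 genes passed limma's test for diet adjusted over the list alone. Heat shock and immediate early genes (-0.24), AhR and NRF2 targets (-0.19) and sinusoidal endothelial markers (-0.24) were also below the random range, and adipose markers (0.33) above it. Among the 65 genes that were higher, 17 were markers of pancreas, muscle or gastric mucosa.

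In knockout mice, 43 genes were at least 2-fold higher on high-fat diet and 38 at least 2-fold lower. Of these, 11 of the higher and 2 of the lower genes were markers of pancreas, muscle or gastric mucosa. Cyp2b9, a cytochrome gene of both the CAR and PXR list and the sex-biased list, was the highest by 3.32, followed by Wee1, Obp2a, Zfp992 and Clec2h. The lowest were Fabp5 (-2.85), the gastric mucin gene Muc6 (-2.06), Apcs (-2.02), Moxd1 (-1.60) and Saa2 (-1.52). The acute phase list was lower, with 18 of 24 members lower and a median of -0.20, and the CAR and PXR list was higher, with 14 of 20 members higher and a median of 0.32 (100th percentile). Antimicrobial proteins (-0.29 over 6 members) and antigen presentation genes (-0.18 over 10) were below the random range. Of the 38 lower genes, 21 were probe sets for small RNAs, and without all small RNA probe sets 17 remained.

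The next comparison asked which transcripts differed with loss of Myd88 on both diets. Of the 10 transcripts highest by the smaller of the 2 differences, 9 were of the exocrine pancreas and 1 was Saa3, a serum amyloid gene. Klk1 was higher in knockout by 3.54 on control diet and 2.16 on high-fat diet, Reg1 by 2.96 and 1.93, Pnliprp1 by 2.60 and 1.75, Saa3 by 3.04 and 1.44, and Clps by 2.35 and 1.39, followed by Cel, Ctrl, Try4, Sycn and Cpa1. The lowest were Ccn1 (-0.71 and -0.57), the muscle creatine kinase gene Ckm (-0.48 and -1.29), the arylsulfatase gene Arsa (-0.65 and -0.48), Madd and Plbd2, of which Ckm alone reached 2-fold, on high-fat diet. At least 2-fold differences of the same sign on both diets were found for 13 genes that were higher and 0 that were lower. Across genes the 2 genotype differences, which share no array, had a Pearson r of 0.031 and a Spearman rho of -0.00134, and 49.9% of genes had the same sign on both diets.

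Interferon stimulated genes were the 1 pathway list above the random range in knockout on both diets, with medians of 0.28 (100th percentile) and 0.20 (98.8th percentile) and 17 and 15 of 18 members higher. Isg15, Ifit1 and Usp18 rose when adjusted over the list alone in limma, by 0.54, 0.53 and 0.68, with an adjusted p of 0.0466 for each; 0 passed over all genes. Sqle, an enzyme of cholesterol synthesis, rose by 0.98 on control diet and 0.80 on high-fat diet (limma, adjusted p over the list alone 0.0102). Saa3 passed among acute phase genes (limma, adjusted p over the list alone 0.0238). Of the 9 pancreas markers, 7 passed for genotype when adjusted over the list alone. Over all genes, limma called 0 for genotype, with a smallest adjusted p of 0.487, and 567 genes had an unadjusted p under 0.05, fewer than the 665 expected by chance. After cyclic loess limma called 3, Klk1, Pnliprp1 and Reg1, all higher and all pancreas markers.

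On control diet, 46 genes were at least 2-fold higher in knockout and 21 at least 2-fold lower. The acute phase response held the highest of them. Saa2 (probe set 17478195) had a log2 value of 4.97 in wild type and 12.34 in knockout, a difference of 7.37. Lcn2, which encodes the iron carrier binding protein lipocalin 2, was higher by 4.30, Orm2, an orosomucoid gene, by 3.32, Mt2 by 2.70 and Mt1 by 2.41. Of 24 measured members, 23 were higher and 9 at least 2-fold higher, with a median of 0.48, above all of the random lists. Moxd1 was higher by 5.00 and Klk1 by 3.54. Complement and coagulation genes had a median of 0.18, with 16 of 22 higher. The lowest were Cyp2b9 (-3.77), Cyp2c38 (-2.09), Slc22a26 (-2.08), Cyp2b13 (-2.02) and Socs2 (-1.61), a gene induced by growth hormone signalling. PPARalpha targets had a median of -0.36 with 23 of 25 lower, among them Pdk4 (-1.60), Acot3 (-1.56) and Acot1 (-1.20), and CAR and PXR targets a median of -0.33 with 17 of 20 lower. This genotype difference and the diet difference in wild type both subtract the wild-type control array, so a feature of that single array enters both. A list outside the random range in both was therefore not found independently. Lipid droplet genes (-0.22), AhR and NRF2 targets (-0.19), lipogenesis (-0.16), glycolysis (-0.14) and bile acid transport (-0.12) were also below the random range, and the unfolded protein response (0.08) above it. Markers of pancreas, muscle or gastric mucosa made up 17 of the 46 higher genes, and without them 29 remained.

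**Figure D2:**
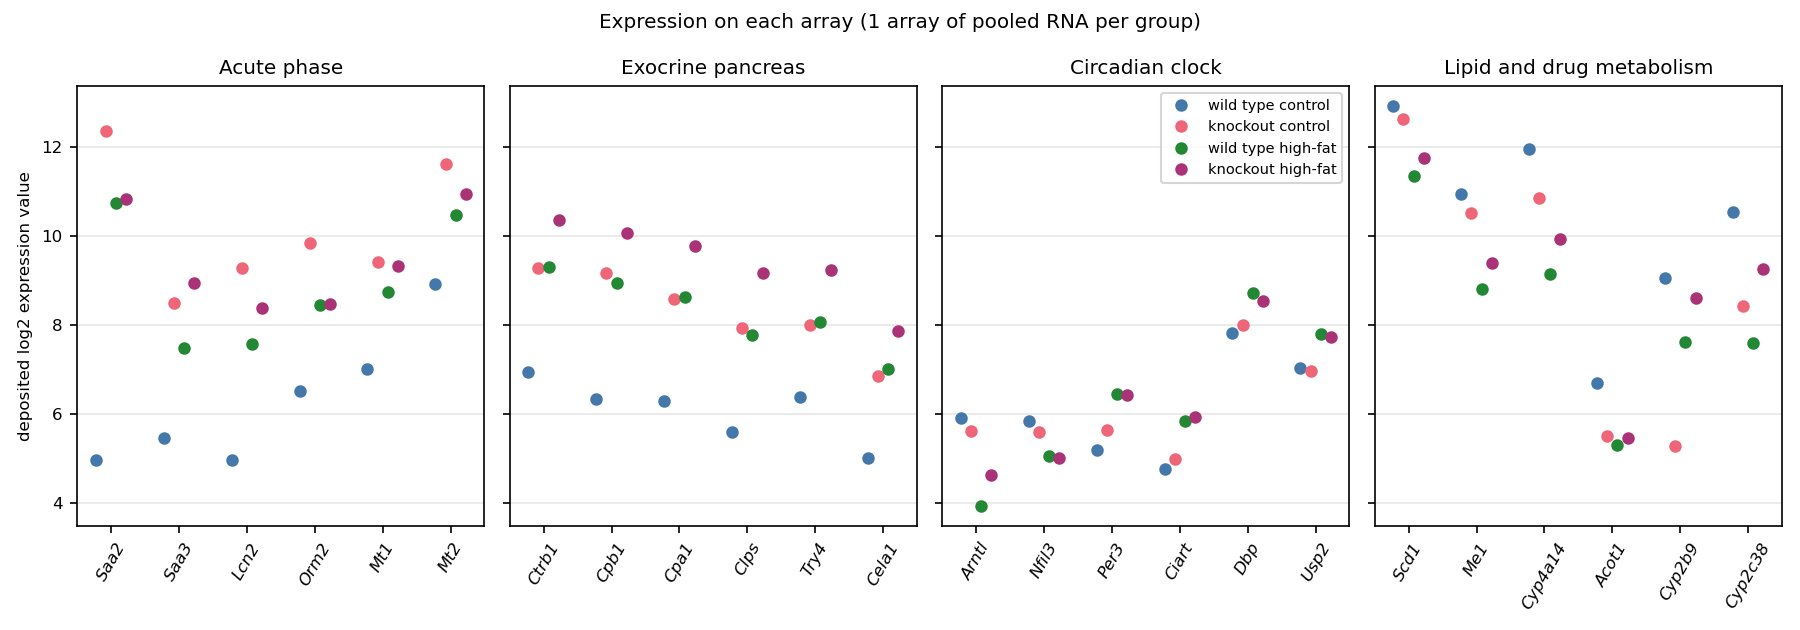
Deposited log2 expression values (y axis) of 24 genes on each of the 4 arrays, 1 point per array, with colours for genotype and diet. The wild-type control array is the lowest for the 6 acute phase and the 6 pancreas genes, with Saa2 at 4.97 against 10.73 to 12.34 on the other arrays, and the clock genes separate by diet.

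On high-fat diet, 30 genes were at least 2-fold higher in knockout and 22 at least 2-fold lower. Klk1, Reg1 and Pnliprp1 were the highest, then Cyp2c38 (1.65) and the steroid hydroxylase gene Cyp17a1 (2.82-fold). The lowest were the skeletal muscle actin gene Acta1 (-1.91), Moxd1 (-1.80), the muscle genes Ttn (2.84-fold lower) and Mb (-1.37), and Btbd35f2 (-1.41). Acta1 was 5.93 on the wild-type high-fat array and between 4.02 and 4.37 on the others. Acute phase genes had a median of 0.12, within the random range, and Saa2 differed by 0.10, Orm2 by 0.04 and Lcn2 by 0.81. CAR and PXR targets were higher, with a median of 0.21 and 15 of 20 members higher, and glucocorticoid and fasting responsive genes had a median of 0.20. Antigen presentation genes (-0.23), complement and coagulation (-0.07), apolipoproteins (-0.10) and markers of T and NK cells (-0.22) were below the random range. PPARalpha targets had a median of 0.07, within it. Without the markers of pancreas, muscle and gastric mucosa 17 higher genes remained, and without small RNA probe sets 12 lower genes remained.

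**Figure D3:**
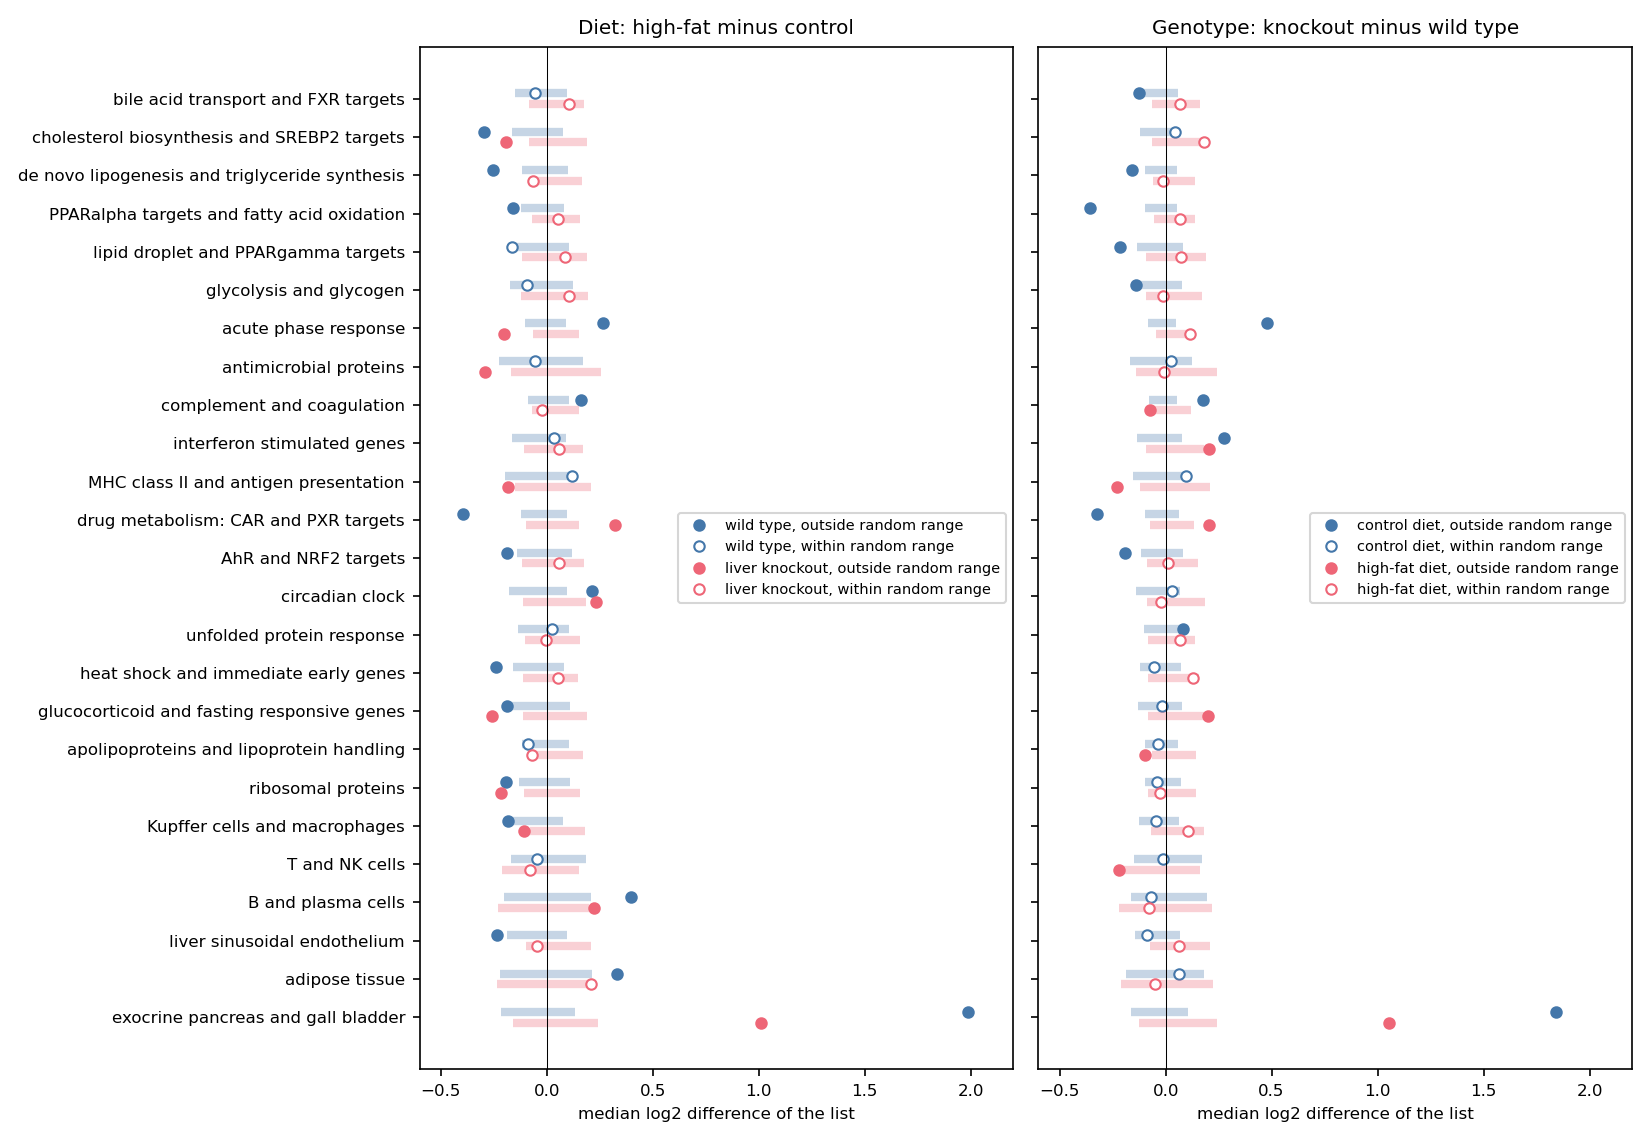
Median log2 difference (x axis) of each gene list that lay outside the random range in any of the 4 differences, for diet (left) and genotype (right); bars span the central 95% of 10000 matched random lists and filled points lie outside them. Acute phase genes lie at 0.48 on control diet and 0.12 on high-fat diet for genotype, and pancreas markers lie farthest to the right in all 4 differences.

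The design also asks whether the response to high-fat diet depended on genotype. With 1 array per group this difference of differences has no test. It draws on 4 arrays, so its 2-fold counts are not on the scale of those from 2 arrays. Divided by 2, it reached 2-fold for 18 genes. The mean diet difference over genotypes did so for 68 and the mean genotype difference over diets for 28. As a signed subtraction, knockout minus wild type, the full difference was positive and at least 2-fold for 88 genes. It was negative and at least 2-fold for 74. A positive value need not mean a stronger response in knockout: Acot1 differed with diet by -1.41 in wild type and -0.04 in knockout. Cyp2b9 (4.76), Cyp2c38 (3.75), Abcd2 (2.58), Acss3 (2.30) and Slc22a26 (2.27) were the highest, and Saa2 (-7.27), Moxd1 (-6.80), Lcn2 (-3.48), Orm2 (-3.28) and the chemokine gene Cxcl1 (-2.64) the lowest. Acute phase genes had a median of -0.66, with 20 of 24 members below 0, and PPARalpha targets and CAR and PXR targets each had a median of 0.46. Genes of complement and coagulation (-0.16) and antigen presentation (-0.32) were below the random range, and lipid droplet genes (0.30) and AhR and NRF2 targets (0.32) above it. Pancreas markers had a median of -0.98. The wild-type control array was the lowest of the 4 for 18 of 24 acute phase genes and the highest for 16 of 25 PPARalpha targets. Independent genes would give 25%, but members of a list can vary together. The counts also restate the differences from this array given above.

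Markers of other tissues differed between the arrays beside these groups. The 9 measured markers of exocrine pancreas and gall bladder had their lowest value on the wild-type control array and their highest on the knockout high-fat array in every case; Ctrb1, a chymotrypsinogen gene, read 6.93 and 10.36 there, and 9.28 and 9.31 on the knockout control and wild-type high-fat arrays. Hepatocyte identity genes had medians between -0.03 and 0.02 in the 4 differences, within the random range. Stellate cell, cholangiocyte and neutrophil markers were within the random range in all 4 differences too. A list of 14 skeletal muscle genes, written after the values were seen, had 12 members highest on the wild-type high-fat array. A list of 6 genes of gastric and gland mucosa, also written afterwards, had 4 members highest on the knockout control array.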

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

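Cyclic loess was set before the data were examined. Its use on explanations, and all other tests of explanations in this part, were chosen after the results they bear on had been seen. The differences between genotypes or diets listed here were not tested, since each group is 1 array.

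Several genes differed at least 2-fold in opposite directions under the same contrast. The difference between the 2 values of a contrast is the same subtraction for diet and for genotype. Equal differences given for both are therefore 1 observation. With high-fat diet, Saa2 was 5.76 higher in wild type and lower by -1.52 in knockout (a difference of -7.27), Moxd1 5.20 and -1.60 (-6.80), Orm2 1.92 and -1.36 (-3.28), and Cyp2b9 -1.44 and 3.32 (4.76). For knockout against wild type, Cyp2c38 was lower by -2.09 on control diet and 1.65 higher on high-fat diet (a difference of 3.75), Abcd2 -1.37 and 1.21 (2.58), C4a 1.09 and -1.14 (-2.23), and Moxd1 5.00 and -1.80 (-6.80). Of the gene lists fixed in advance, those that lay outside the random range in opposite directions were acute phase genes for diet (0.26 in wild type and -0.20 in knockout, with a median difference of -0.66), CAR and PXR targets for diet (-0.39 and 0.32, median difference 0.46) and for genotype (-0.33 on control diet and 0.21 on high-fat diet, median difference 0.46), and complement and coagulation for genotype (0.18 and -0.07, median difference -0.16). Of the lists written after the data were examined, female-biased liver genes did so for diet (-1.03 and 0.29) and for genotype (-1.22 and 0.26), with a median difference of 1.48, and genes of gastric and gland mucosa for diet (0.40 and -0.72) and for genotype (0.85 and -0.25), with a median difference of -1.07.

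In the probe sets without a gene name, which no comparison used, 12 were at least 2-fold higher and 21 at least 2-fold lower on high-fat than on control diet in both genotypes, and 13 were at least 2-fold higher and 7 at least 2-fold lower in knockout than in wild type on both diets.

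The first pattern is that most acute phase transcripts were lowest on the wild-type control array (18 of 24) and most were highest on the knockout control array (18 of 24), with exceptions such as Saa3, highest on the knockout high-fat array, and Apcs, lowest on the wild-type high-fat array. The list's median genotype difference on control diet was 0.48 before and 0.48 after cyclic loess. This cannot decide on scaling between arrays, since the deposited values were already normalised by quantiles. Scaling shared by genes of like expression is argued against: the random range of lists matched on expression was -0.08 to 0.05 for this difference. Over the 24 list members the genotype difference on high-fat diet minus that on control diet had a median of -0.66, whose sign follows from this order of the arrays for the members that have it, so it is no test of the pattern. An effect of the knockout that depends on diet, which the design names, stays open and untested, and so does an effect of the knockout that is alike on both diets together with differences between the pools. One or a few animals of a pool with inflammation could give the same values, and with 1 array per group these cannot be told apart.

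The second pattern is that pancreas transcripts differed between arrays, with the 9 markers between 3.51 and 6.93 on the wild-type control array and between 4.18 and 10.36 on the knockout high-fat array. The median genotype difference over both diets was 1.40 before and 1.38 after cyclic loess. This cannot decide on scaling between arrays either, since the deposited values were already normalised by quantiles. Scaling shared by genes of like expression is argued against: the random range of lists matched on expression was -0.11 to 0.13 for this difference. The wild-type control array was the lowest and the knockout high-fat array the highest for 9 of 9 markers fixed in advance and for 22 of 23 markers of the wider list. The wider list was written after the data were examined and shares markers with the fixed list, so its count is no independent support. On a linear scale, the excess over the wild-type control array was 0.416 of that on the knockout high-fat array for the knockout control array (quartiles 0.376 and 0.455 over the 14 genes of the wider list that were at least 4-fold apart on these arrays) and 0.372 for the wild-type high-fat array (quartiles 0.263 and 0.409). Tissue carried over from the pancreas could give this order, and so could expression of these genes in the liver that follows both diet and genotype; with 1 array per group these cannot be told apart.

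The third pattern is that clock transcripts differed with diet. Noise of single arrays that is independent between genes is argued against: over 17 members the diet differences in the 2 genotypes had a Pearson r of 0.91 (0.89 without Arntl), above 0.79, the upper end of the central 95% of matched random lists. The same direction in both genotypes for 16 of the 17 had been seen before this r was chosen, so the r is not independent of it. Of 16 members sorted by textbook phase, 14 were lower where they peak with Arntl or higher where they peak opposite to it, in both genotypes; the exceptions were Npas2 and Nr1d1. Another time of day at collection could give this, and so could a shift of the clock by the diet, which the design names. These cannot be told apart here, because each diet has its own arrays and no collection time was used.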

How the results depend on the processing

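The alternatives without tissue markers and without small RNA probe sets were chosen after seeing the data; the others were planned. Of 130 recomputed counts, 101 stayed within 1.5 times the reported value. After cyclic loess, limma called 41 genes higher and 29 lower for diet in place of 0 and 0, and 3 higher for genotype in place of 0; of the 70 for diet, 70 had an unadjusted p under 0.05 before loess, 11 were tissue markers and 7 small RNAs. The smallest adjusted p over the other settings ranged from 0.0993 to 0.216 for diet and from 0.294 to 0.992 for genotype. The genes with an unadjusted p under 0.05 for genotype numbered 934 with no filter and 376 with the filter at the 60th percentile, where more and fewer genes were tested. Without small RNA probe sets, 17 genes were lower with diet in knockout and 12 lower for genotype on high-fat diet. Without markers of pancreas, muscle and gastric mucosa, 29 genes were higher in knockout on control diet and 17 on high-fat diet. At 1.5-fold, the counts higher and lower were 224 and 336 for diet in wild type, 304 and 229 for diet in knockout, 120 and 115 for genotype on control diet, 279 and 134 for genotype on high-fat diet, and 682 and 414 for the difference of differences. At 3-fold they were 24 and 16, 6 and 7, 27 and 6, 5 and 3, and 17 and 20, in the same order. These last changes follow from the threshold; for the loess counts the cause was not tested. The correlation of the genotype differences across genes, 0.031, was -0.00134 as Spearman's rho, and the other 9 recomputed correlations moved by less than 0.1. The differences of Myd88 had the same sign after loess. Of 236 recomputed gene differences, 234 kept their direction and their side of 2-fold and 2 fell under it. Of 299 recomputed list medians outside the random range, 293 remained outside in the same direction and 6 came to lie within it. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers. Leaving out an array was not run, since it leaves the additive fit with no residual degrees of freedom. Signal over background limits the dim genes and was not analysed here.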

Other observations

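Small nucleolar RNA probe sets were lower on the knockout high-fat array. Over 67 of them, the median difference was -0.68 for diet in knockout and -0.57 for genotype on high-fat diet, against -0.21 for diet in wild type and -0.09 for genotype on control diet. At least 2-fold lower were 15 of the 67 for diet in knockout, 8 for genotype on high-fat diet, 2 for diet in wild type and 0 for genotype on control diet, and 1 was at least 2-fold higher, for diet in wild type. The values come from total RNA, and no test was run.

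Liver genes with higher expression in females than in males, a list of 16 written after the data were examined, had a median difference of -1.03 for diet in wild type, 0.29 for diet in knockout, -1.22 for genotype on control diet and 0.26 for genotype on high-fat diet. Of the 16, 12 were highest on the wild-type control array. The list fixed in advance of sex-biased and growth hormone dependent genes, which mixes both directions, had medians between -0.06 and 0.00 and was within the random range in all 4 differences. Xist, expressed in female cells, read between 3.07 and 3.23 on the 4 arrays, and the Y-linked genes Eif2s3y, Uty and Kdm5d read between 7.67 and 8.23, 6.38 and 7.30, and 4.82 and 5.67.

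The skeletal muscle list had median differences of 0.75 for diet in wild type and -0.90 for genotype on high-fat diet, against -0.07 and 0.04 for the other differences, and the list of gastric and gland mucosa 0.40 for diet in wild type, -0.72 for diet in knockout, 0.85 for genotype on control diet and -0.25 for genotype on high-fat diet. The wider pancreas list had medians of 1.47 and 0.97 for diet and 1.66 and 1.13 for genotype.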
